A study of Mus musculus with 14 samples.

How the data were processed

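The series measured gene expression in mouse hearts at E12.5 (the embryonic day) on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample and 14 arrays in all. Per the labels, total RNA was isolated with a PicoPure kit, and 1 ng was amplified with NuGEN WT-Ovation FFPE V2 reagents and labelled with biotin through the Encore module. The labels give 4 genotypes. They are Irx5+/- (3 arrays), Irx3-/-;Irx5+/- (4 arrays), Irx5-/- (3 arrays) and Irx3-/-;Irx5-/- (4 arrays), and Irx5+/- was the reference because the series text makes it so. The labels do not say whether each array is a separate embryo, so p-values measure only the spread between these samples.

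The deposited values are log2 intensities per probe set that the authors made with RMA (background correction, quantile normalization and a summary per probe set) over all arrays together, using the R package affy. Per the file headers, the authors then left out probe sets with no group mean above 3 and fitted limma models with Benjamini-Hochberg adjustment. The versions of RMA, affy and limma that they used are not given in the sources used here, and neither is the genome build of the array annotation. In the value table, 0 probe sets had no group mean above that floor. Values were used as deposited, with no further scaling. Intensities are not counts, so no depth applies, and the number of arrays limits the precision.

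The value table holds 28763 probe sets. The platform's probe table pairs 21776 of them with exactly 1 gene symbol and 1592 with several, and 5395 have no symbol there. Of the probe sets with 1 symbol, 21685 were found by gene ID in the reference gene table (assembly GRCm38.p6, used only for names and for which genes neighbour each other), and 91 were not. Where a gene had several probe sets (998 genes), the one with the highest mean over all arrays was kept, which left 19931 genes. Array medians ran from 7.89 to 7.99, and correlations between arrays from 0.962 to 0.987.

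The main test was limma (version 3.58.1 in R 4.3.3), with a mean per group over all 14 arrays, 10 residual degrees of freedom and moderated variances (3.50 prior degrees of freedom). The median residual SD was 0.186 on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, with no minimum fold. Comparisons were Irx3-/-;Irx5+/-, Irx5-/- and Irx3-/-;Irx5-/- each against Irx5+/-, the double mutant against Irx3-/-;Irx5+/- and against Irx5-/-, and the interaction, which is the effect of losing Irx3 in Irx5-/- hearts minus its effect in Irx5+/- hearts. Errors given with a log2 difference are standard errors of that fit, and errors given with a group mean are SDs.

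The comparisons, the 42 gene lists and the rule for naming genes were chosen before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, 2-sided, adjusted over all 252 pairs of list and comparison. Camera with an estimated correlation and limma's fry were alternatives. Members were also counted after adjustment over the list alone. Named genes were Irx1 to Irx6 in each comparison, up to 12 called genes per direction by size of change, and up to 4 called members per list. Where no member of a list passed, the 2 with the smallest p could be named, and where fewer than 5 genes passed in a comparison, the 5 with the smallest p per direction. Col4a1 was added after the results were seen, as the lower extracellular matrix gene with the smallest p in its comparison. For the interaction the 10 genes with the smallest p were named. Predicted genes, olfactory and vomeronasal receptors and small RNAs were left out of the genes named by size of change or smallest p. They stayed in the tests and in the counts of called genes.

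Correlations of log2 differences across genes were set beside the mean of 100 simulations with no effect on the same shared arrays, and of 20 simulations for each array left out. Genes were independent in these simulations too. The procedure was tested on simulated data with the residual spread of each gene and independent genes, with 200 genes shifted per comparison. It recovered 76 to 87 of 100 genes shifted by a fold of 2 and 95 to 98 of 100 shifted by a fold of 4, with 5 to 16 false calls among 179 to 198. With so many genes shifted, the adjusted threshold was easier to reach than in the real comparisons, which called 0 to 4 genes. These shares therefore do not carry over to them, and a low real count does not exclude changes of a fold of 2 or 4. Gja5 in double mutants against Irx5+/-, at a log2 difference of 2.10, was not called (adjusted p = 0.122 in limma). A shifted list was found each time, and 0 of 40 unshifted lists were called in each of the comparisons simulated. Because the simulated genes were independent, this does not test lists whose genes vary together. Splits of the real arrays other than the real one called a median of 6, 11, 6, 8, 10 and 9 lists, in the order of the comparisons above.

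Alternatives were quantile normalization again, centring arrays on 1 median, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, all probe sets, only the groups compared, eBayes with trend and robust settings, array weights, a term for the replicate number, leaving out Xist and the Y genes, an adjusted p under 0.10, a minimum fold of 1.5, and leaving out each array in turn. A sex term, a muscle content term (each array's mean of the sarcomere list), an exact permutation of array means per list, and leaving out Irx3-/-;Irx5+/- replicate 4 where it does not enter a comparison were added after seeing the data. Sex was read from Xist and 4 Y-linked genes. The sarcomere mean itself differed between genotypes, so the muscle content term can also take up genotype effects. Values with that term are therefore not corrected genotype effects. The text file of example probe sets was not used beyond its header.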

Results

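The series compared hearts of mouse embryos that carried different numbers of working copies of Irx3 and Irx5, neighbouring genes for homeodomain transcription factors of the Iroquois family. Its title concerns cooperative and antagonistic roles of both genes in heart morphogenesis and postnatal physiology. The 14 arrays comprised 3 Irx5+/- hearts as reference, 4 Irx3-/-;Irx5+/- hearts, 3 Irx5-/- hearts and 4 Irx3-/-;Irx5-/- hearts at E12.5. Each array gave log2 intensities for 19931 named genes, and array medians ran from 7.89 to 7.99. The first principal component held 23.5% of the variance, with Irx5+/- replicate 3 at -34.2 and Irx5-/- replicate 2 at 33.4. By Xist and Y-linked genes, the reference held 2 female and 1 male samples, Irx3-/-;Irx5+/- 3 and 1, Irx5-/- 1 and 2, and the double mutant 3 and 1.

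The Irx3 signal averaged 8.47 ± 0.05 (SD, n = 3) in Irx5+/- hearts, 7.97 ± 0.14 (SD, n = 4) in Irx3-/-;Irx5+/- hearts, 8.19 ± 0.06 (SD, n = 3) in Irx5-/- hearts and 7.73 ± 0.11 (SD, n = 4) in double mutants. Irx3 fell by 0.74 ± 0.10 (SE) in double mutants against the reference, with all 4 arrays below all 3 reference arrays (adjusted p = 0.0201). In Irx3-/-;Irx5+/- hearts it lay at -0.50 ± 0.10 (SE) against the reference and did not pass over all genes (adjusted p = 0.673), although all 4 arrays were below the reference and it passed within the Iroquois family, 1 of 6 members adjusted over the list alone. In Irx5-/- hearts, whose label names no Irx3 mutation, it lay at -0.27 ± 0.10 (SE, adjusted p = 0.400 in limma) and did not pass. All 3 of those arrays (8.14 to 8.25) were nevertheless below all 3 reference arrays (8.43 to 8.53), so a lower Irx3 signal was not particular to the Irx3-/- groups. The Irx5 signal averaged 8.32 ± 0.11 (SD, n = 3) in the reference, 8.26 ± 0.06 (SD, n = 4) in Irx3-/-;Irx5+/- hearts, 8.04 ± 0.27 (SD, n = 3) in Irx5-/- hearts and 8.05 ± 0.38 (SD, n = 4) in double mutants. Its differences from the reference were -0.29 ± 0.19 (SE, adjusted p = 0.588) in Irx5-/- hearts and -0.28 ± 0.18 (SE, adjusted p = 0.532) in double mutants, and neither passed. Without Irx3-/-;Irx5-/- replicate 3 the latter was -0.10, and without Irx5-/- replicate 2 the former was -0.44. Irx5 of Irx5-/- replicate 2 (8.34) and of Irx3-/-;Irx5-/- replicate 1 (8.20) lay inside the reference range of 8.19 to 8.41, and that of Irx3-/-;Irx5-/- replicate 2 (8.43) above it. The array carried 1 probe set for each gene, and whether it lies in the deleted part is not given in the sources used here. A probe set outside that part checks nothing about a genotype. The array labelled Irx3-/-;Irx5+/- replicate 4 has a title and genotype of that group but a description of Irx5-/-, and its Irx3 signal of 8.17 lay within the 8.14 to 8.25 of the Irx5-/- arrays, above the 7.87 to 7.93 of the other Irx3-/-;Irx5+/- arrays. Its Irx5 signal of 8.31 lay within the 7.86 to 8.34 of the Irx5-/- arrays and beside the 8.21 to 8.31 of its own group. On the second principal component it lay at 11.51, within the -4.20 to 15.32 of its own group and above the -31.99 to 1.37 of the Irx5-/- arrays.

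**Figure D1:**
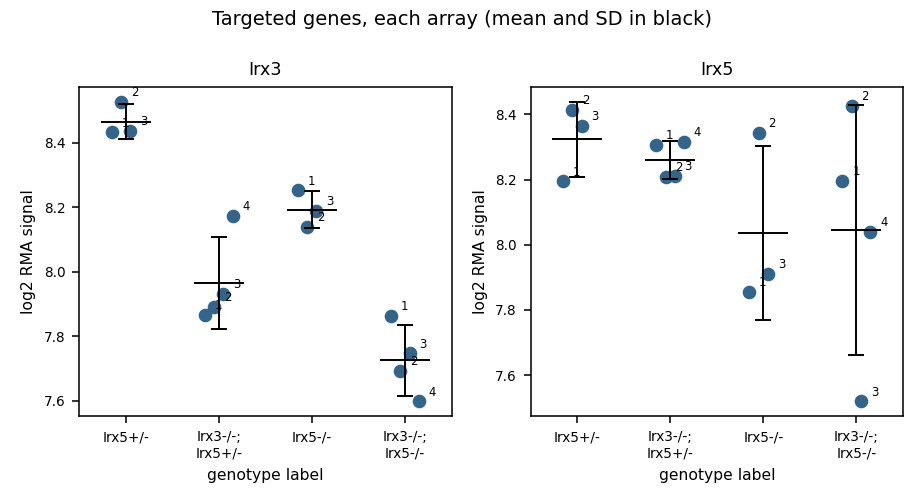
Log2 RMA signal of Irx3 and Irx5 on each of the 14 arrays by genotype label, with group mean and SD in black. Irx3 was 8.43 to 8.53 in Irx5+/- and 7.60 to 7.86 in Irx3-/-;Irx5-/- hearts, while Irx5 ranges overlapped between groups, at 8.19 to 8.41 and 7.52 to 8.43.

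The comparison of Irx3-/-;Irx5+/- with Irx5+/- hearts asks what the loss of Irx3 does where 1 copy of Irx5 remains. No gene passed (0 of 19931 in limma, smallest adjusted p = 0.673), while 1010 had an unadjusted p under 0.05 against 996.55 expected by chance. Among the genes nearest to passing were Grpel1, a mitochondrial import co-chaperone, at 0.67 ± 0.13 (SE), Amz2, a metalloprotease, at 0.76 ± 0.15, Klhl23 at 0.71 ± 0.15 and Fdft1, squalene synthase of the cholesterol pathway, at 0.58 ± 0.13. On the lower side lay Irx3, Fen1, a DNA replication nuclease, at -0.76 ± 0.15, and Endod1 at -0.63 ± 0.13. Genes of the sarcomere, which drives contraction, averaged 0.81 higher, with all 32 members above 0 and 0 passing over all genes or adjusted over the list alone. Examples were Tnni1 at 0.98 ± 0.31 and Myl7 at 0.97 ± 0.33, the latter 0.61 without Irx5+/- replicate 3. Camera called the sarcomere list with its preset correlation (adjusted p = 6.1e-18), but not otherwise (adjusted p = 0.744 with an estimated correlation). Oxidative phosphorylation genes averaged 0.44 higher (Cox6a2 0.94 ± 0.36, Atp5o 0.59 ± 0.24), with 0 of 23 passing on either count, and adjusted p = 0.825 with an estimated correlation. Endothelial markers averaged -0.14 (Cd34 -0.61 ± 0.23, Sox18 -0.43 ± 0.19, or -0.28 without Irx3-/-;Irx5+/- replicate 2), with 0 of 30 passing on either count, and adjusted p = 0.825 with an estimated correlation. Within the DNA replication list, Fen1 was the 1 of 23 members to pass adjusted over the list alone, and the list had a mean of 0.00 and a median of -0.04. Within the trabecular myocardium list of 15 genes, Irx3 passed on the low side and Gja5, the connexin 40 gap junction gene at 1.53 ± 0.47, on the high side, both only adjusted over the list alone. Without Irx5+/- replicate 3 or 1 the sarcomere mean was 0.35 or 1.24 and the oxidative phosphorylation mean 0.24 or 0.66, and the endothelial mean was -0.04 without Irx5+/- replicate 2 and -0.22 without Irx3-/-;Irx5+/- replicate 4. Altogether camera called 9 lists, 7 higher and 2 lower, and 0 with an estimated correlation.

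The 3 reference arrays differed from each other in muscle genes. Their sarcomere list means, relative to the mean of all arrays, were 0.14, -0.66 and -1.64 for replicates 1, 2 and 3. The oxidative phosphorylation list followed, at 0.00, -0.49 and -0.83. With each array's sarcomere mean as a term, the oxidative phosphorylation list turned to -0.10 ± 0.12 (SE) in Irx3-/-;Irx5+/- and -0.01 ± 0.13 in Irx5-/- hearts against the reference, from 0.44 and 0.55. Every comparison with Irx5+/- hearts rests on those arrays, and in the mutant groups the sarcomere list ran from -0.39 in Irx3-/-;Irx5+/- replicate 3 to 0.88 in Irx5-/- replicate 2.

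The comparison of Irx5-/- with Irx5+/- hearts asks what the loss of the second copy of Irx5 does. Endothelial and endocardial markers averaged -0.54, with 29 of 30 members below 0 and all 3 Irx5-/- arrays below all 3 reference arrays in the list mean. Of those 30 genes, 0 passed over all genes and 9 were lower adjusted over the list alone, among them Plvap, a protein of fenestrated endothelium, at -0.97 ± 0.25 (SE) and Flt1, a VEGF receptor, at -0.91 ± 0.25. Camera gave adjusted p = 9.0e-11 with the preset correlation and adjusted p = 0.744 with an estimated correlation. Fdft1 lay at 0.89 ± 0.14, Klhl23 at 0.96 ± 0.16 and Extl3, a heparan sulfate enzyme, at 1.19 ± 0.20, and Ets1, an endothelial transcription factor, at -0.75 ± 0.13, with adjusted p from 0.159 to 0.226. Tbx20, a cardiac transcription factor at 0.77 ± 0.19, passed adjusted over the list alone as 1 of 27 cushion genes, 1 of 14 compact myocardium genes and 1 of 25 cardiac transcription factors, while 0 of those passed over all genes. Cardiac transcription factors averaged 0.27, and their call ended at adjusted p = 0.734 with an estimated correlation. G2 and M phase genes averaged 0.19 (Bub1 0.49 ± 0.12, Top2a 0.26 ± 0.11), and 0.09 ± 0.10 with the sarcomere term, with 1 of 23 higher adjusted over the list alone and 0 over all genes, and adjusted p = 0.796 with an estimated correlation. Sarcomere genes averaged 0.84 (Des 0.92 ± 0.32, Tnni1 0.96 ± 0.34), with 0 of 32 passing on either count, and adjusted p = 0.796 with an estimated correlation. Without Irx5-/- replicate 2 the sarcomere mean was 0.45, Des 0.59, the oxidative phosphorylation mean 0.21 and the G2 and M phase mean 0.12. The sarcomere mean was 0.38 without Irx5+/- replicate 3, where Tnni1 was 0.63 and the oxidative phosphorylation mean 0.35, and 1.27 without Irx5+/- replicate 1. Genes near Irx3 and Irx5 had a mean of -0.02, and 2 of 21 passed adjusted over the list alone, Bbs2 at 0.62 ± 0.11 and Sall1 at -0.92 ± 0.24, with 0 over all genes. Altogether 0 genes passed in limma, 2122 had an unadjusted p under 0.05 and camera called 10 lists, 8 higher and 2 lower, and 0 with an estimated correlation. Without Irx5+/- replicate 1 or without Irx5-/- replicate 2 the gene count was 1.

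The comparison of Irx3-/-;Irx5-/- with Irx5+/- hearts asks what the loss of both genes does. Hmcn1, which encodes the extracellular matrix protein hemicentin 1, fell by 0.85 ± 0.09 (SE), from 12.80 ± 0.01 (SD, n = 3) to 11.95 ± 0.12 (SD, n = 4), or 1.81-fold (adjusted p = 0.00539). Fdft1 rose by 1.06 ± 0.13, from 9.44 ± 0.16 to 10.50 ± 0.15 (adjusted p = 0.0107), and Klhl23 by 1.04 ± 0.15, from 8.51 ± 0.15 to 9.55 ± 0.09 (adjusted p = 0.0436). Irx3 was the fourth gene called, and for each of the 4 genes every double mutant array lay on the same side of every reference array. Among the next, without passing, were Siva1 at 0.70 ± 0.11, Hectd2 at 1.52 ± 0.24, Polr3c at 0.59 ± 0.10, Cav1, the main protein of caveolae, at -1.13 ± 0.19 and Sncaip at -1.04 ± 0.19, with adjusted p from 0.0675 to 0.0807. In limma, 4 genes passed, 2 higher and 2 lower, and 2684 had an unadjusted p under 0.05.

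Gene lists of this comparison were broad, although Irx3 was the only member called over all genes. Endothelial and endocardial markers averaged -0.62, with all 30 members below 0 and the double mutant arrays below the reference arrays in the list mean. Of them 21 were lower adjusted over the list alone and 0 over all genes, with Cd34 at -1.06 ± 0.23 (SE) and Ecscr at -0.98 ± 0.23 as examples (adjusted p = 1.83e-14 preset, adjusted p = 0.734 with an estimated correlation). Sarcomere genes averaged 1.09, with 25 of 32 higher adjusted over the list alone and 0 over all genes, such as Myl7 at 1.57 ± 0.33 and Tnni1 at 1.23 ± 0.31 (adjusted p = 8.93e-19 preset, adjusted p = 0.744 with an estimated correlation). Oxidative phosphorylation genes averaged 0.70, with 19 of 23 higher adjusted over the list alone and 0 over all genes (Cox6a2 1.45 ± 0.36, Atp5o 0.85 ± 0.24), and adjusted p = 0.744 with an estimated correlation. With each array's sarcomere mean as a term, the oxidative phosphorylation list moved to -0.02 ± 0.13 and the glycolysis list from 0.67 to 0.18 ± 0.15. Because sarcomere genes differed by 1.09 between these groups, the term cannot part muscle content from genotype here. Before that term, 14 of 23 glycolysis and hypoxia genes were higher adjusted over the list alone and 0 over all genes (Egln3 1.12 ± 0.26, Slc2a3 1.26 ± 0.35), with adjusted p = 0.744 with an estimated correlation. G2 and M phase genes averaged 0.35, all 23 above 0, 7 of them higher adjusted over the list alone and 0 over all genes (Bub1 0.64 ± 0.11, Ube2c 0.73 ± 0.18), with adjusted p = 0.734 with an estimated correlation. The sarcomere term left that list at 0.23 ± 0.11. DNA replication genes averaged 0.24, with 5 of 23 higher adjusted over the list alone and 0 over all genes (Cdc6 0.87 ± 0.18, Rrm1 0.48 ± 0.12), and adjusted p = 0.744 with an estimated correlation. Extracellular matrix genes averaged -0.28 but moved both ways, with 2 higher and 5 lower of 28 adjusted over the list alone and 0 over all genes (Nid2 0.48 ± 0.13, Vcan 0.76 ± 0.22, and on the lower side Col4a1 -0.40 ± 0.12), and adjusted p = 0.825 with an estimated correlation. The sarcomere term turned the extracellular matrix list to 0.05 ± 0.14. Cushion and valve mesenchyme genes averaged 0.27, and 0.79 ± 0.24 with the sarcomere term, with 3 of 27 higher adjusted over the list alone and 0 over all genes, among them Tbx20 at 0.87 ± 0.17 and Msx2 at 0.43 ± 0.12, and adjusted p = 0.825 with an estimated correlation. Atrioventricular canal and conduction genes were not called as a list (adjusted p = 0.118), although 4 of 22 were higher adjusted over the list alone, with Gja5 at 2.10 ± 0.47 and Tbx3 at 0.57 ± 0.14, and 0 over all genes. Trabecular genes were not called either (mean 0.27, median 0.03, and means of 0.45 and 0.16 without Irx5+/- replicate 1 and 3), with 3 higher and 3 lower of 15 adjusted over the list alone and Irx3 called over all genes. In all camera called 16 lists, 12 higher and 4 lower, and 0 with an estimated correlation or with fry.

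The count of 4 genes depended on single arrays. It was 0 without Irx5+/- replicate 2, 23 without Irx5+/- replicate 1, 10 without Irx3-/-;Irx5-/- replicate 2, and 1 without Irx3-/-;Irx5-/- replicate 3 or without replicate 4. Klhl23 lost its call in each of the 8 fits with an array left out (adjusted p from 0.0571 to 0.138), Hmcn1 only without Irx5+/- replicate 2 (adjusted p = 0.0629), and Fdft1 without Irx5+/- replicate 2 and without Irx3-/-;Irx5-/- replicate 3 or 4 (adjusted p from 0.0586 to 0.0866). Irx3 lost its call without Irx5+/- replicate 2 or 3 and without Irx3-/-;Irx5-/- replicate 3 or 4 (adjusted p from 0.0616 to 0.0985). With the sarcomere term, or with a term for the replicate number, the count was 0, and the 16 lists became 10 without Irx5+/- replicate 2. Without Irx5+/- replicate 3 the sarcomere mean was 0.63 and the cushion mean 0.41, and the latter was 0.16 without Irx3-/-;Irx5-/- replicate 4.

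**Figure D2:**
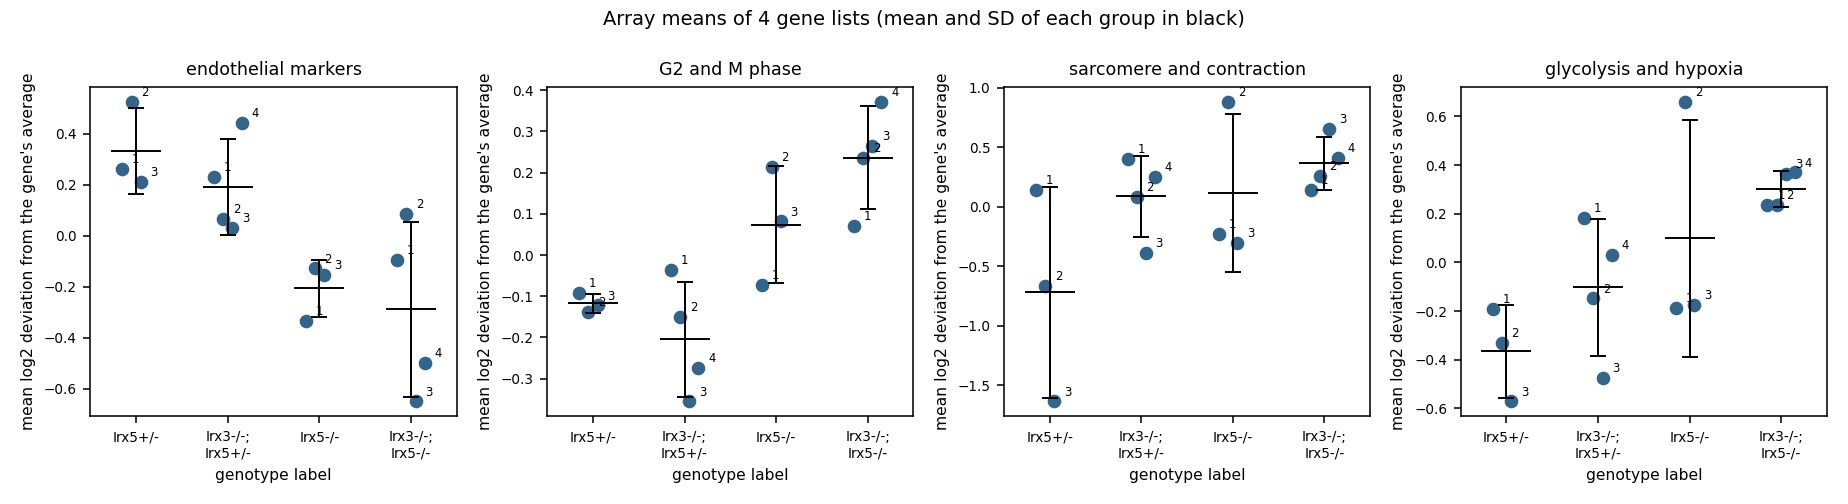
Mean log2 signal of named gene lists on each array, relative to the mean of all arrays, by genotype label. Endothelial means were 0.21 to 0.53 in Irx5+/- and -0.65 to 0.09 in Irx3-/-;Irx5-/- hearts, and G2 and M phase means were -0.36 to -0.04 in Irx3-/-;Irx5+/- and 0.07 to 0.37 in Irx3-/-;Irx5-/- hearts.

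The comparison of Irx3-/-;Irx5-/- with Irx3-/-;Irx5+/- hearts asks what the loss of the last copy of Irx5 does where Irx3 is absent. Hmcn1 fell by 0.65 ± 0.08 (SE), from 12.60 ± 0.10 (SD, n = 4) to 11.95 ± 0.12 (SD, n = 4), with all 4 double mutant arrays below the other 4 (adjusted p = 0.0478). It was the 1 gene called in limma, 1528 had an unadjusted p under 0.05, and the count was 0 when any 1 of the 8 arrays was left out, with Hmcn1 at adjusted p from 0.069 to 0.353. Among genes that did not pass, Mcm8 lay at 0.92 ± 0.15, Tacc3, a spindle protein, at 0.55 ± 0.10, Msx2 at 0.59 ± 0.11 and Cav1 at -0.83 ± 0.17, with adjusted p from 0.261 to 0.281. G2 and M phase genes averaged 0.44 higher in double mutants, with 22 of 23 above 0 and all 4 double mutant arrays above the other 4 in the list mean (exact permutation p = 0.0286, the smallest these groups can give). Of them 15 were higher adjusted over the list alone and 0 over all genes, with Top2a, a topoisomerase of dividing cells, at 0.51 ± 0.10 and Prc1, a cytokinesis protein, at 0.80 ± 0.17 (adjusted p = 2.35e-22 preset, adjusted p = 0.293 with an estimated correlation). DNA replication genes averaged 0.24, with 4 of 23 higher adjusted over the list alone and 0 over all genes (Rrm1 0.53 ± 0.11, Uhrf1 0.47 ± 0.11), and adjusted p = 0.734 with an estimated correlation. Histone genes averaged 0.42, all 10 above 0 with 0 passing on either count (H1f3 0.45 ± 0.16, H1f5 0.46 ± 0.19), and adjusted p = 0.734 with an estimated correlation. Endothelial markers averaged -0.48, with 10 of 30 lower adjusted over the list alone and 0 over all genes (Ecscr -0.95 ± 0.21, Npr3 at a fold of 0.499), and adjusted p = 0.744 with an estimated correlation. Cushion mesenchyme genes averaged 0.31, with 2 of 27 higher adjusted over the list alone and 0 over all genes (Msx2, and Tbx20 0.63 ± 0.16), and adjusted p = 0.825 with an estimated correlation. Sarcomere genes averaged 0.28, with 0 of 32 passing on either count (Acta1 0.56 ± 0.25, Tcap 0.81 ± 0.38), and adjusted p = 0.825 with an estimated correlation. Without Irx3-/-;Irx5+/- replicate 3 the histone mean was 0.25 and the sarcomere mean 0.12, without Irx3-/-;Irx5-/- replicate 3 the latter was 0.18, and without Irx3-/-;Irx5-/- replicate 4 the cushion mean was 0.20. In all camera called 14 lists, 11 higher and 3 lower, and 0 with an estimated correlation.

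**Figure D3:**
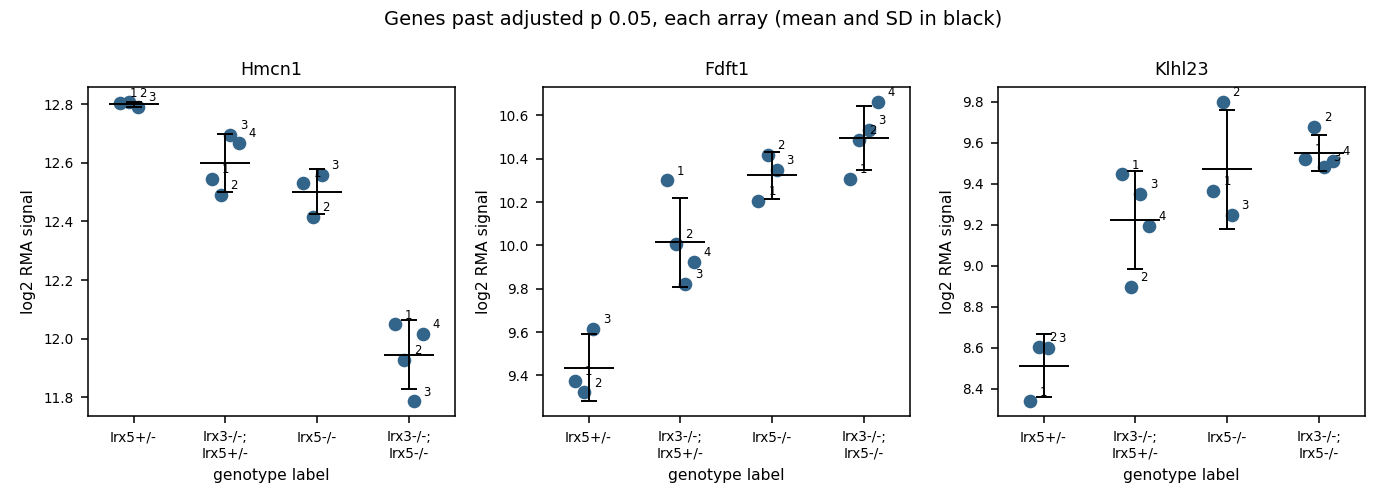
Log2 RMA signal of Hmcn1, Fdft1 and Klhl23 on each array by genotype label, with group mean and SD in black. Hmcn1 averaged 12.80 in Irx5+/-, 12.60 in Irx3-/-;Irx5+/- and 11.95 in Irx3-/-;Irx5-/- hearts, and the Irx5-/- arrays lay at 12.41 to 12.56.

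The comparison of Irx3-/-;Irx5-/- with Irx5-/- hearts asks what the loss of Irx3 does where Irx5 is absent. No gene passed (0 in limma, with 724 at an unadjusted p under 0.05). The smallest adjusted p was 0.160, for a gene of the classes left unnamed. Hmcn1 lay at -0.56 ± 0.09 (SE, adjusted p = 0.310), Irx3 at -0.47 ± 0.10 and Lama2, a basement membrane laminin, at -1.03 ± 0.21 (both adjusted p = 0.796). On the higher side, also at adjusted p = 0.796, were Tbx3, a conduction system transcription factor, at 0.63 ± 0.14 and Ccnd1, cyclin D1, at 0.58 ± 0.13. Immediate early and stress genes averaged -0.38, with 2 of 24 lower adjusted over the list alone and 0 over all genes (Egr1 -1.15 ± 0.33, Fosb -1.31 ± 0.38), and adjusted p = 0.744 with an estimated correlation. Extracellular matrix genes averaged -0.21, and -0.14 ± 0.11 with the sarcomere term, with Lama2 the 1 of 28 lower adjusted over the list alone and 0 over all genes, and adjusted p = 0.825 with an estimated correlation. G2 and M phase genes averaged 0.16 (Ccnb2 0.36 ± 0.16, Ube2c 0.35 ± 0.18), with 0 of 23 passing on either count, and adjusted p = 0.744 with an estimated correlation. Without Irx5-/- replicate 1, Ccnb2 lay at 0.15, Ube2c at 0.19 and Fosb at -0.86, and the means of G2 and M phase, extracellular matrix and immediate early genes were 0.09, -0.08 and -0.17. Without Irx5-/- replicate 2 Ube2c lay at 0.61 and the extracellular matrix mean at -0.42, and without Irx5-/- replicate 3 the extracellular matrix and immediate early means were -0.13 and -0.63. Camera called 9 lists, 4 higher and 5 lower, 0 with an estimated correlation, and 14 without Irx5-/- replicate 2, while the gene count was 1 without Irx3-/-;Irx5-/- replicate 4.

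The interaction asks whether the effect of losing Irx3 differs with the Irx5 genotype, the comparison that bears on the cooperative and antagonistic roles in the title. No gene passed (0 in limma, with 806 at an unadjusted p under 0.05), and every adjusted p was close to 1. The smallest p-values belonged to Scn3a, a sodium channel gene, at 0.57 ± 0.13 (SE), Gabra4 at -1.38 ± 0.31, Atraid at -0.81 ± 0.19 and Bach1 at 0.66 ± 0.16. Irx3 itself lay at 0.03 ± 0.14. G2 and M phase genes had a mean interaction of 0.25 (Cenpe 0.49 ± 0.16, Kif20a 0.66 ± 0.23), with 0 of 23 passing on either count, and adjusted p = 0.744 with an estimated correlation. Loss of Irx3 went with a mean of -0.09 for these genes in Irx5+/- hearts, and 0.16 in Irx5-/- hearts. The first was -0.14 without Irx3-/-;Irx5+/- replicate 1 and -0.04 without replicate 3. Sarcomere genes had a mean of -0.56 (Cacna1c -0.65 ± 0.38, Des -0.71 ± 0.42), with 0 of 32 passing on either count, and adjusted p = 0.825 with an estimated correlation. Without Irx5-/- replicate 2, the sarcomere mean was -0.17, Cacna1c -0.29 and Des -0.37. The mean was -0.10 without Irx5+/- replicate 3, where Cacna1c was -0.43, and -0.99 without Irx5+/- replicate 1. Within the DNA replication list, Fen1 at 0.89 ± 0.22 was the 1 of 23 higher adjusted over the list alone, with 0 over all genes. Camera called 6 lists, 1 higher and 5 lower, 0 with an estimated correlation, and 10 without Irx3-/-;Irx5-/- replicate 3.

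Across the 19931 genes, log2 differences from the reference resembled each other between mutants. The correlation across genes, which are not independent replicates, was 0.646 between Irx3-/-;Irx5+/- and Irx5-/- hearts. Simulations with no effect, shared reference arrays and independent genes averaged 0.535. Genes that vary together could move that value, so it is a rough guide, and the excess over it was not tested. The correlation was 0.678 between Irx3-/-;Irx5+/- hearts and double mutants (0.571 simulated) and 0.761 between Irx5-/- hearts and double mutants (0.535 simulated). The covariances were 0.0362 (0.0229 simulated), 0.0412 (0.0228 simulated) and 0.0583 (0.0229 simulated) in that order. Without Irx5-/- replicate 2 the first correlation was 0.484 (0.475 simulated for the arrays left) and the third 0.552 (0.476 simulated). Without Irx5+/- replicate 3 the first was 0.665 (0.633 simulated) and the second 0.677 (0.667 simulated). Fdft1 and Klhl23 were higher in all 3 mutant groups, at 0.58, 0.89 and 1.06 and at 0.71, 0.96 and 1.04, in the order Irx3-/-;Irx5+/-, Irx5-/- and double mutant, and passed only in the double mutant. Double mutants lay at 0.48 ± 0.12 (SE, adjusted p = 0.389) for Fdft1 and 0.33 ± 0.14 (SE, adjusted p = 0.624) for Klhl23 against Irx3-/-;Irx5+/- hearts, and at 0.17 ± 0.13 and 0.08 ± 0.15 against Irx5-/- hearts, none of which passed. Irx5-/- and Irx3-/-;Irx5+/- hearts were not compared with each other. No division of the 3 reference arrays leaves 2 in each part, so how much of the excess they carry was not separated.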

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

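Of the tests in this part, the comparison of endothelial with cushion mesenchyme genes, the sex term and the muscle content term were chosen after the results were seen. So was the second principal component set beside the split with the most genes.

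Of 60 groups of 4 arrays examined for a single array far from the rest, 2 held one, where chance gives about 1 in 20. Both were Irx3-/-;Irx5+/- replicate 3, whose extracellular matrix list mean was 0.33 against -0.10 to -0.03 in the other 3 arrays of its group, and whose Notch signalling list mean was 0.27 against -0.02 to 0.02. In 6 lists the effect of losing Irx3 differed between Irx5-/- and Irx5+/- hearts in camera with the preset correlation, with mean interactions of -0.56 for sarcomere, 0.25 for G2 and M phase, -0.29 for oxidative phosphorylation, -0.39 for fatty acid oxidation, -0.29 for immediate early and stress genes and -0.33 for p53 targets. With the muscle content term oxidative phosphorylation turned to 0.08 ± 0.15 (SE) and fatty acid oxidation moved to -0.09 ± 0.19 (SE). Without Irx5-/- replicate 2 sarcomere, oxidative phosphorylation and fatty acid oxidation were -0.17, 0.05 and -0.05, without Irx5+/- replicate 3 they were -0.10, -0.09 and -0.25, and without Irx5-/- replicate 1 or 3 immediate early and stress genes were -0.08 or -0.54. None of the 6 held with an estimated correlation (smallest adjusted p = 0.734), and 74 of 100 splits of the arrays called as many lists, the highest other split 19, so chance cannot be excluded for them.

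Endothelial and endocardial markers were lower in Irx3-/-;Irx5-/- than in Irx5+/- hearts by a list mean of -0.62 ± 0.18 (SE). Cushion mesenchyme genes did not fall alike, and the endothelial minus cushion difference was -0.89 between the groups. It was -0.46 ± 0.41 (SD) in 4 double mutant and 0.43 ± 0.38 (SD) in 3 reference arrays (exact permutation p = 0.0286, the smallest possible). These lists were set against each other after both means were seen, so that p-value adds no support. Cushion genes also stand for only some non-muscle cells, and extracellular matrix genes averaged lower in the same groups. The endothelial list stayed at -0.65 ± 0.24 (SE) with the muscle content term, so a linear muscle trend does not account for it. With the sex term the list stayed at -0.64 ± 0.17 (SE). Double mutants held 3 female and 1 male samples and the reference 2 and 1. With shares so close the term could hardly move the estimate, so it says little about sex. A lower share of some non-muscle cells, a change in endothelium itself and a difference in dissection that touches endothelium alone stay open and untested. The count of 16 lists called in Irx3-/-;Irx5-/- against Irx5+/- was reached by 1 of 35 splits, the real one, and the highest other split called 15. That share is under 0.05 but is the smallest that 35 splits can give, and several counts were tested, so chance is not excluded. Of the 16, 0 held with an estimated correlation or fry, and 10 lists were called without Irx5+/- replicate 2.

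G2 and M phase genes were higher in Irx3-/-;Irx5-/- than in Irx3-/-;Irx5+/- hearts by a list mean of 0.44 ± 0.09 (SE). The array with a conflicting description does not carry it, since the mean was 0.42 ± 0.10 (SE) without that array. It was 0.41 ± 0.08 (SE) with the muscle content term, so a linear muscle trend does not account for it. Both groups hold 3 female and 1 male samples, so their sex shares do not differ and the sex term (0.44 ± 0.09, SE) tests nothing further, and a small difference in embryo age stays open and untested. The count of 14 lists called in that comparison was reached by 5 of 35 splits, the highest other calling 17, so chance cannot be excluded for the count.

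Irx3 of the array labelled Irx3-/-;Irx5+/- replicate 4 lay inside the range of the Irx5-/- arrays. If the array were an Irx5-/- sample, its other genes could place it with that group. Its held-out position between the other Irx3-/-;Irx5+/- arrays (0) and the Irx5-/- arrays (1) was 0.30, but the test cannot decide, because the other Irx3-/-;Irx5+/- arrays took 0.61 to 0.65 and the Irx5-/- arrays 0.10 to 0.56. Whether the label or the description is right therefore cannot be told apart.

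The other counts were compared with splits of the same arrays in the same way. For Irx3-/-;Irx5-/- against Irx5+/- the 4 genes were reached by 1 of 35 splits, the real one, and the highest other split called 2. That share is again under 0.05 but the smallest that 35 splits can give, and with several counts tested it does not exclude chance. For Irx3-/-;Irx5-/- against Irx3-/-;Irx5+/- the 1 gene was reached by 3 of 35 splits (highest other 1), and chance cannot be excluded. For Irx3-/-;Irx5+/- against Irx5+/- the 9 lists were reached by 9 of 35 splits (highest other 15), so chance cannot be excluded, and the 0 genes by 35 of 35 (highest other 1). For Irx3-/-;Irx5-/- against Irx5-/- the 9 lists were reached by 24 of 35 splits (highest other 19), so chance cannot be excluded, and the 0 genes by 35 of 35 (highest other 9). The split with 9 genes set Irx5-/- replicate 2 and Irx3-/-;Irx5-/- replicates 1 and 3 apart from the other 4 arrays. Neither sex (1 male of 3, 2 of 4) nor sarcomere list means (0.14 to 0.88, -0.30 to 0.41) parted them. The second principal component of all arrays did, at 0.47 to 11.50 against -31.99 to -7.44. The split was picked for calling the most genes, and the component was looked up afterwards, so that match adds no support. What sets these arrays apart was not tested. For Irx5-/- against Irx5+/- the 10 splits are too few for a share under 0.05, with 0 genes in the real split and 0 in the highest other, and 10 lists in the real split and 15 in the highest other, as 10 and 6 splits reached those counts. For the interaction, 100 of 100 splits reached the real count of 0 genes, the highest other calling 1. Any split reaches a count of 0, so for those counts the splits decide nothing.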

How the results depend on the processing

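The sex term, the muscle content term, the exact permutation of array means and leaving out Irx3-/-;Irx5+/- replicate 4 where it does not enter were chosen after the results were seen, and all other alternatives before. Over the 198 gene and comparison pairs named, Irx3 and Irx5 apart, 3729 values under alternatives kept direction and side of the threshold, 38 lost the call, 7 gained it and 42 changed sign. Most of the values that kept their side are genes that were not called and stayed so. The only calls to lose were Hmcn1, Fdft1 and Klhl23 in Irx3-/-;Irx5-/- against Irx5+/- and Hmcn1 against Irx3-/-;Irx5+/-. All 38 losses fall on those calls, so the totals do not show that calls are stable. For arrays the limit is their number and signal over background.

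For Irx3-/-;Irx5-/- against Irx5+/-, the 4 genes became 2 with the mean of a gene's probe sets, 14 with all probe sets (a count of probe sets, not of genes), 15 with only the groups compared, 7 with array weights, 22 at an adjusted p under 0.10, 0 with the replicate block and 0 with the muscle content term. The looser threshold is a cause by construction, and otherwise the cause was not tested. For Irx3-/-;Irx5-/- against Irx3-/-;Irx5+/-, the 1 gene became 5 with all probe sets (again a count of probe sets) and 0 with median centring, the dimmest genes left out, the mean of probe sets, only the groups compared, the replicate block, the sex term or the muscle content term. For Irx3-/-;Irx5-/- against Irx5-/-, the 0 genes became 2 with trend and robust settings. Lists fell to 0 in all 6 comparisons with an estimated correlation and with fry, and to 0 in the 5 comparisons given an exact permutation, which the interaction was not. Its smallest possible p before adjustment is 0.0286, or 1 in 10 for Irx5-/- against Irx5+/-, so its 0 says nothing about the lists. The 10 lists of Irx5-/- against Irx5+/- became 5 with quantile normalization and 3 with the muscle content term, and the 16 lists of Irx3-/-;Irx5-/- against Irx5+/- became 7 with the muscle content term. Irx3 in Irx3-/-;Irx5-/- against Irx5+/- kept its direction but not its call with only the groups compared (-0.74, adjusted p = 0.0759), the replicate block (-0.75, adjusted p = 0.153) and the muscle content term (-0.72, adjusted p = 0.153). The cause was not tested.

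Leaving out 1 array at a time gave 0 to 0 genes for Irx3-/-;Irx5+/- against Irx5+/-, 0 to 1 for Irx5-/- against Irx5+/-, 0 to 23 for Irx3-/-;Irx5-/- against Irx5+/-, 0 to 0 for Irx3-/-;Irx5-/- against Irx3-/-;Irx5+/-, 0 to 1 for Irx3-/-;Irx5-/- against Irx5-/- and 0 to 0 for the interaction. Lists ran from 6 to 10, 7 to 13, 10 to 16, 10 to 15, 7 to 14 and 4 to 10 in that order. Irx3 in Irx3-/-;Irx5-/- against Irx5+/- ran from -0.79 to -0.70, Irx5 in Irx3-/-;Irx5-/- against Irx5-/- from -0.12 to 0.18, and the interaction from -0.013 to 0.10 for Irx3 and from -0.054 to 0.25 for Irx5. The correlation of differences from the reference ran from 0.484 to 0.747 between Irx3-/-;Irx5+/- and Irx5-/- hearts, 0.580 to 0.773 between Irx3-/-;Irx5+/- hearts and double mutants and 0.552 to 0.823 between Irx5-/- hearts and double mutants.

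The following values changed sign, and the cause was not tested. Irx5 in Irx3-/-;Irx5-/- against Irx5-/- was -0.0042 with quantile normalization and -0.10 with the sex term, the Irx3 interaction -0.014 with array weights and the Irx5 interaction -0.015 with the sex term. With quantile normalization, Irx1 and Irx2 in Irx5-/- against Irx5+/- were 0.0050 and -0.012, Irx2 in Irx3-/-;Irx5-/- against Irx3-/-;Irx5+/- -0.010 and the Irx2 interaction 0.0017. With array weights, Irx1 in Irx3-/-;Irx5-/- against Irx5+/- was -0.047 and Irx2 in Irx3-/-;Irx5-/- against Irx3-/-;Irx5+/- -0.056, and with the replicate block Irx6 in Irx3-/-;Irx5+/- against Irx5+/- was 0.018. With the muscle content term, Irx4 and Irx6 in Irx3-/-;Irx5+/- against Irx5+/- were -0.34 and 0.056, Irx2 and Irx4 in Irx5-/- against Irx5+/- -0.062 and -0.21, Irx1, Irx4 and Myh7 in Irx3-/-;Irx5-/- against Irx5+/- -0.036, -0.063 and -0.056, Irx2 in Irx3-/-;Irx5-/- against Irx3-/-;Irx5+/- -0.025 and the Irx2 interaction 0.037.

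Leaving out 1 array at a time moved these across 0. In Irx5-/- against Irx5+/-, Irx1 from -0.13 to 0.028, Irx2 from -0.071 to 0.098 and Irx4 from -0.00064 to 0.66. In Irx3-/-;Irx5+/- against Irx5+/-, Irx4 from -0.080 to 0.44 and Irx6 from -0.12 to 0.062. In Irx3-/-;Irx5-/- against Irx5+/-, Irx1 from -0.088 to 0.091. In Irx3-/-;Irx5-/- against Irx3-/-;Irx5+/-, Irx2 from -0.094 to 0.067. In Irx3-/-;Irx5-/- against Irx5-/-, Irx1 from -0.033 to 0.15 and Irx6 from -0.0071 to 0.15. In the interaction, Irx2 from -0.11 to 0.073 and Irx4 from -0.19 to 0.47.

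The replicate numbers do not pair the arrays. Over 19 same-number pairs, residual correlations ran from -0.179 to 0.191 (mean -0.0194), against a mean of 0.00661 over 54 other pairs, and 2 of 14 arrays correlated best with their own number, so replicate block values say little. Irx3 and Irx5 have 1 probe set each, so a version per probe set gave no new value, and for the interaction only the groups compared is the fit itself. Under each scaling the median log2 difference of all genes lay between -0.0284 and 0.0109.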

Other observations

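Of the tests in this part, the muscle content term was chosen after the results were seen, and the test of genes around Irx3 and Irx5 before.

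Epicardial markers were uneven between arrays. The list mean of Irx3-/-;Irx5-/- replicate 1 was 1.04 relative to all arrays, against -0.48 to 0.21 in the other double mutants, and Irx5-/- replicate 2 lay at -0.68. The list averaged 0.34 in double mutants against the reference, and 0.96 ± 0.34 (SE) with the muscle content term, but 0.06 without Irx3-/-;Irx5-/- replicate 1, 0.21 without Irx5+/- replicate 1 and 0.57 without Irx3-/-;Irx5-/- replicate 3. Its members included Krt19 at 0.99 ± 0.30 (SE) and Tcf21 at 1.36 ± 0.54, and 0 of 20 members passed over all genes or adjusted over the list alone, with adjusted p = 0.825 with an estimated correlation. Erythroid genes were not called in any comparison. In Irx3-/-;Irx5+/- hearts against the reference, the embryonic globin genes Hbb-y and Hba-x lay at 3.07 ± 1.09 and 1.86 ± 0.63. Neither passed (adjusted p = 0.899 and 0.878 in limma), and embryonic globins were not tested as a group. The erythroid list had a mean of 0.39 and a median of 0.04 there.

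Potassium channel genes, which shape repolarization, were not called as a list in any comparison. In double mutants against the reference, 0 of 28 passed over all genes or adjusted over the list alone, Kcnd1 lay at -0.59 ± 0.19 (SE) and Kcnj2 at 0.70 ± 0.24, and the list had a mean of 0.07 and a median of -0.04, which differ in sign. Retinoic acid signalling genes were not called either, although 1 of 16 was higher and 1 lower adjusted over the list alone in that comparison, Nr2f1 at 0.71 ± 0.17 and Nr2f2 at -0.63 ± 0.19, and 0 over all genes.

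Chromosomal neighbours carried along with the Irx3 and Irx5 mutations could differ between Irx5-/- and Irx5+/- hearts. Of the 100 genes around Irx3 and Irx5, 14 had an unadjusted p under 0.05 in that comparison, against a median of 11 and a highest of 21 in 350 windows of 100 genes elsewhere, which puts them at the 83.1 percentile and below the 95th that the explanation needed. Bbs2 had the smallest p among them. A count over 100 genes cannot exclude an effect on a few of them. Against the reference, Irx6 lay at -0.38 ± 0.15 (SE, adjusted p = 0.418 in limma) in Irx5-/- hearts and -0.29 ± 0.14 (SE, adjusted p = 0.404) in double mutants. In Irx3-/-;Irx5+/- hearts Irx6 lay at -0.02 ± 0.14 (SE), and it passed in none of these comparisons.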
